A study of Homo sapiens with 6 samples.

How the data were processed

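Expression was measured in NB4 cells on 6 Affymetrix arrays, 1 per time: untreated cells (0 h) and cells harvested 4, 12, 24, 48 and 72 h after all-trans retinoic acid (ATRA) was added at 1e-06 M. Per the labels, total RNA was extracted with the RNeasy Protect Midi kit and turned into biotin-labelled cRNA by one-cycle synthesis. Samples were grouped by the time in their labels, and there were no replicates.

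The deposited values are log2 probe set summaries, and RMA is named in the submitters' processing notes. The RMA version, the software, the background method and a genome build are not given in the sources used here. The log2 unit was checked against the values, which lay between 1.39 and 13.6 with array medians of 3.64 to 3.69. RMA makes the arrays' distributions alike, so a shift of most transcripts in 1 direction would be hidden in these values. The number of arrays limits the precision.

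The values held 54675 probe sets. The platform annotation gave 1 gene to 41097 of them, several genes to 1801 and none to 11777. Control probe sets (62, of which 6 had 1 gene) were left out of the gene comparisons, which left 41091. Symbols of 41037 probe sets were updated through Entrez identifiers to the gene table of assembly GRCh38.p14, used for names alone. No coordinates are printed, since no build is named for the probe sets. Each of the 19775 genes was represented by its probe set with the highest mean over the 6 arrays. A gene was kept when its highest value reached the median of all values, 3.66. This kept 13594 genes, of which 8529 had several probe sets. Probe sets with several genes or none were not analysed here, so some list members have no value.

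Each ATRA time was compared with the untreated array as a difference of log2 values, counted at 2-fold or more. A difference of single arrays has no replicate check and gets no p-value. Fold values with an end below 3.66 were computed with that end set to 3.66 and are given as at least that value, a choice made after seeing the data, while log2 differences, counts and ranks use the values as deposited. As a rough reference, unchanged arrays were simulated 100 times from each gene's residual SD around its trend. That SD also holds any departure from a line, so it can overstate noise. The trend over time order (0 to 5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), and slopes were called at a Benjamini-Hochberg adjusted p under 0.05. This fit was tested on simulated data with 13594 genes: it recovered 81 of 100 genes with a slope of 0.3 per step and 97 of 100 with 0.6, with 16 false calls.

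Gene lists were fixed before the data were examined: retinoid response, PML-RARA partners and corepressors, primary granule, secondary and tertiary granule, mature neutrophil, NADPH oxidase, myeloid transcription factors, stem and progenitor, MYC and ribosome biogenesis, DNA replication, mitosis, cell cycle inhibitors, interferon-stimulated, antigen processing and immunoproteasome, inflammatory cytokines and chemokines, apoptosis, coagulation and fibrinolysis, lysosome and autophagy, monocyte and macrophage, B cell, T and NK cell, erythroid, megakaryocyte, fibroblast and epithelial, hypoxia, ER stress and amino acid response, and cholesterol synthesis. A list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. In a test on simulated lists, 2 of 40 unchanged lists fell outside percentiles 2.5 to 97.5 and 20 of 20 shifted lists lay above. A list's mean profile was correlated with time order (Pearson r and Spearman rho), with exact two-sided permutation p-values over all 720 orders and Benjamini-Hochberg adjustment over the 27 lists. Symbol-based gene families were added before any gene's value was seen, and lists of aryl hydrocarbon receptor targets and further hypoxia-inducible genes after 4 h values of other genes, such as CYP1A1 and ADM, had been seen, but before those of their own members.

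Genes were named by a rule fixed with the lists: the 12 largest rises and falls at 4, 24 and 72 h, the 5 largest at 12 and 48 h, up to 4 members per list with the largest difference at 72 h (other members of lists of 12 or fewer genes where the text needs them), and CYP26A1, RARA, PML, MYC, CEBPE, MPO, ELANE, ITGAM, CD38 and TGM2. The last part of the list rule left a choice, and ANKRD37, CDKN1A, PRTN3 and AZU1 were picked under it after their values were seen. Other genes, also chosen after their values were seen, are named only to spell out counts of called list members or in the closing section. Monocyte markers below the filter, and secondary granule genes below it or without a call, are named too.

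Other settings tried were cyclic loess, a shift to an equal median of the hybridisation controls (18 probe sets of bioB, bioC, bioD and cre), the mean of all probe sets, leaving out x_at probe sets, which are prone to cross-hybridisation, no filter and a filter at percentile 75, other fold thresholds (1.5 and 3), a baseline of the 0 and 4 h arrays, other time scales, and leaving out arrays. The bioC control split the arrays, so alternatives with the 4 h array as baseline, with the bioC level as a covariate, within arrays of 1 bioC level, without the 12 h array for list trends, with early genes also 2-fold different at 12 h, and with a shift to an equal mean of the controls without bioC (14 probe sets) were added after seeing the data. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.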

Results

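NB4 is a human acute promyelocytic leukaemia line that carries the PML-RARA fusion, and ATRA is a ligand of retinoic acid receptors that makes such cells mature toward neutrophils. The series followed transcripts in untreated cells and after 4, 12, 24, 48 and 72 h in 1e-06 M ATRA, with 1 array per time and 6 arrays in all. No value below has a replicate, and time in ATRA and time in culture ran together. Array medians lay between 3.64 and 3.69 on the log2 scale. The spiked bioC control averaged 8.06 on the 0 and 12 h arrays and 7.04 on the 4, 24, 48 and 72 h arrays, so these sets of arrays may differ technically.

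At 4 h, which asks what differed soonest after ATRA, ID1, an inhibitor of basic helix-loop-helix factors, was at least 58.7-fold higher than in untreated cells. Folds given as at least a value have an end below the filter on low values (3.66), which was set to that level. The monocyte-attracting chemokine CCL2 was 38.9-fold higher, the xenobiotic-metabolising enzyme CYP1A1 30.5-fold, and the SRC-family kinase FGR 19.2-fold. LFNG, VSIR, TOGARAM2, NCF1, ASB2, PRAM1, INAVA and LRG1 were 10.3- to 16.5-fold higher. NCF1, a subunit of the NADPH oxidase, has near-identical pseudogenes that its probe set may also read. TENT5C was 18.1-fold lower, GSAP 8.52-fold, RNF24 7.54-fold and the phosphatase PTPRE at least 5.73-fold. RNF24 was within 1.02-fold of untreated at 12 h and 3.55- to 5.71-fold lower at 24 to 72 h, which follows the bioC level of the arrays. STK17B, ADM, SLC2A3, EBF3 and TNF were 4.94- to 5.82-fold lower, and RAVER2, PGBD5 and PRSS12 at least 4.80-, 3.87- and 2.89-fold.

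Among the fixed lists, retinoid response genes already stood apart at 4 h, with a median log2 difference of 0.90 over 16 members and 7 of them 2-fold or more higher. NADPH oxidase genes (0.50), mature neutrophil genes (0.30) and inflammatory genes (0.30) were also at percentile 99.65 or above among random lists, though the neutrophil and inflammatory medians turn negative with the control shift without bioC described below. MYC and ribosome biogenesis genes (-0.32), stem and progenitor genes (-0.57) and cholesterol synthesis genes (-0.48) were at percentile 0.09 or below, and their medians turn positive with the shift on all controls. CEBPB, a factor of granulocyte and monocyte maturation, was higher by 3.12, and the cell cycle inhibitor CDKN2D by 2.22. In all, 236 genes were 2-fold or more higher at 4 h and 246 lower, where simulated unchanged arrays gave 126.9 and 126.9. The simulation used each gene's residual SD around its trend. That SD also holds step-like or passing changes, so these simulated counts do not measure noise alone.

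By 12 h the 5 largest measured differences were those of ALOX5AP and CCL2 (72.6- and 72.5-fold higher), FGR (64.5-fold), ID1 (at least 55.8-fold) and NCF1 (47.7-fold). ALOX5AP is needed for leukotriene synthesis. TENT5C (7.34-fold), GSAP (7.13-fold), CYP1B1 (5.87-fold), HDC (5.86-fold) and PGBD5 (at least 3.87-fold) were lower. The 12 h array shares the bioC level of the untreated array, and 313 genes were 2-fold or more higher and 263 lower on it. With the mean of the 0 and 4 h arrays as baseline, genes higher at 12 h numbered 208 and genes lower at 12 h 134.

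At 24 h S100A8, a calcium-binding neutrophil protein, was 177-fold higher and its partner S100A9 64.2-fold. ALOX5AP (137-fold), the transglutaminase TGM2 (103-fold), CCL2 (86.3-fold), FGR (77.0-fold), NCF1 (72.9-fold), the survival gene BCL2A1 (65.3-fold), LAMB3, DEFA4, PADI4 (at least 36.2-fold) and CYP4F3 (at least 15.5-fold) made up the rest of the 12 largest as measured. On the lower side GSAP differed by at least 13.4-fold, ZBTB16 by at least 9.16-fold, TENT5C by 9.16-fold and CYP1B1 by 8.35-fold. HDC, MS4A3, CA2, EBF3, TBL1X, CDC42EP3 and IGFBP4 were 6.30- to 8.34-fold lower, and CYTL1 at least 2.43-fold. There were 456 higher and 270 lower genes at 24 h, and 341 and 129 against the 4 h array, which shares its bioC level.

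At 48 and 72 h interferon-related transcripts joined the neutrophil genes. IFIT3 was 131-fold higher at 48 h and 415-fold at 72 h, after 4.45-fold at 24 h. At 72 h S100A8 was 604-fold higher, TGM2 451-fold, CCL2 439-fold, IFIT1 322-fold and ALOX5AP 236-fold. The chemokine CXCL10 was at least 483-fold higher, IFI27 at least 423-fold, IFIT2 at least 254-fold, OAS1 at least 250.1-fold, CLC at least 240.0-fold and IFI44 at least 147-fold. The protease inhibitor CST7 was at least 57.1-fold lower at 72 h, ASS1, an enzyme of arginine synthesis, 56.0-fold, NT5DC2 at least 46.9-fold, MS4A3 at least 40.9-fold, BCAT1 27.5-fold and the transcription factor WT1 25.8-fold. GJA1 was 19.9-fold lower, EBF3, CA8, MEGF6, GSAP and PHACTR3 at least 13.4- to 22.0-fold, and S1PR3 at 48 h at least 10.7-fold. The counts were 793 higher and 610 lower genes at 48 h, and 1479 and 1656 at 72 h. Against the 4 h array they were 665 and 319 at 48 h, and 1371 and 1413 at 72 h.

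**Figure D1:**
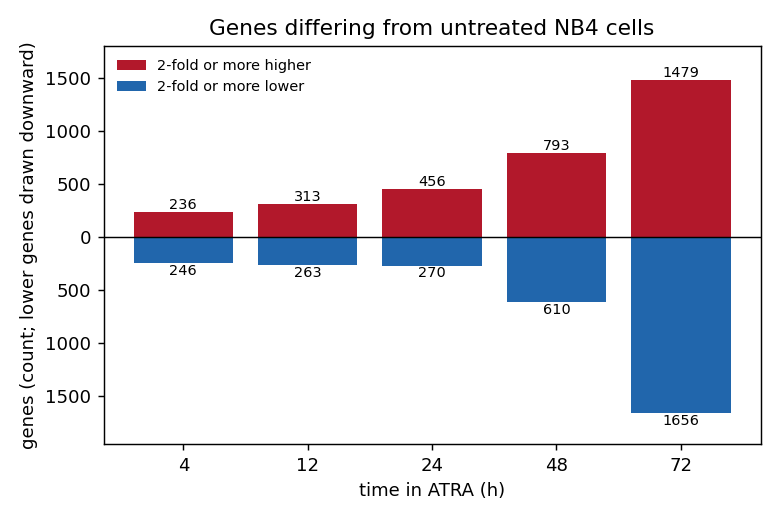
Number of genes 2-fold or more higher (red, upward) or lower (blue, downward) than in untreated cells at each time in ATRA (h), 1 array per time. Higher genes number 236 at 4 h and 1479 at 72 h, and lower genes 246 and 1656.

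The split of higher against lower genes depends on the scaling, because the spiked controls moved between arrays. Equalising the median of all 18 hybridisation controls, which bioC drives, shifts every gene relative to untreated by 0.71 at 4 h, -0.15 at 12 h, 0.83 at 24 h, 1.0 at 48 h and 0.66 at 72 h. Equalising the mean of bioB, bioD and cre without bioC shifts genes by -0.41, -0.08, -0.48, -0.36 and -0.56. With the first and the second shift in turn, genes higher at 4 h numbered 3182 and 104 and genes lower at 4 h 52 and 910. At 12 h the second shift left 269 genes higher at 12 h, while genes lower at 12 h were 445 and 355. The genes higher at 24 h were 4323 and 237, and genes lower at 24 h 57 and 1351. The genes higher at 48 h were 7054 and 529, and genes lower at 48 h 91 and 1464. The genes higher at 72 h were 3319 and 905, and genes lower at 72 h 494 and 3895. Changes below are therefore relative to the arrays' common level, and a list's place among random lists is less affected.

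The trend over time order tests whether a straight line through the 6 arrays has a slope. A gene that changes in a step or reaches a plateau can be called too. The immunoproteasome subunit PSMB9 rose by 1.30 ± 0.05 per step (log2, SE, limma adjusted p = 3.98e-05) and PLAAT4, a retinoid-responsive phospholipase, by 1.19 ± 0.05 (limma adjusted p = 5.25e-05). S100A8 rose by 2.03 ± 0.16 per step and TGM2 by 1.94 ± 0.15 (limma adjusted p = 0.000503 for each). Myeloperoxidase, MPO, fell by 0.39 ± 0.02 per step and MS4A3 by 1.19 ± 0.07 (limma adjusted p = 0.000274 for each). Of 13594 genes, limma called 1132 rising and 1341 falling, and 4449 had an unadjusted p under 0.05. ID1, CYP1A1, CEBPB, TENT5C and TNF, which differed early, were not called.

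Of the arrays left out singly, 72 h lowered the trend counts most, to 440 rising and 269 falling genes. They were 867 and 536 without the untreated array, 809 and 863 without 4 h, 884 and 1034 without 12 h, 1077 and 1268 without 24 h, and 836 and 954 without 48 h. With the bioC level as a covariate 523 genes rose and 876 fell, and within the 4, 24, 48 and 72 h arrays 299 and 128. Genes with a rising trend were 1025 and genes with a falling trend 47 with the shift on all controls, and 747 and 3279 with the shift without bioC.

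**Figure D2:**
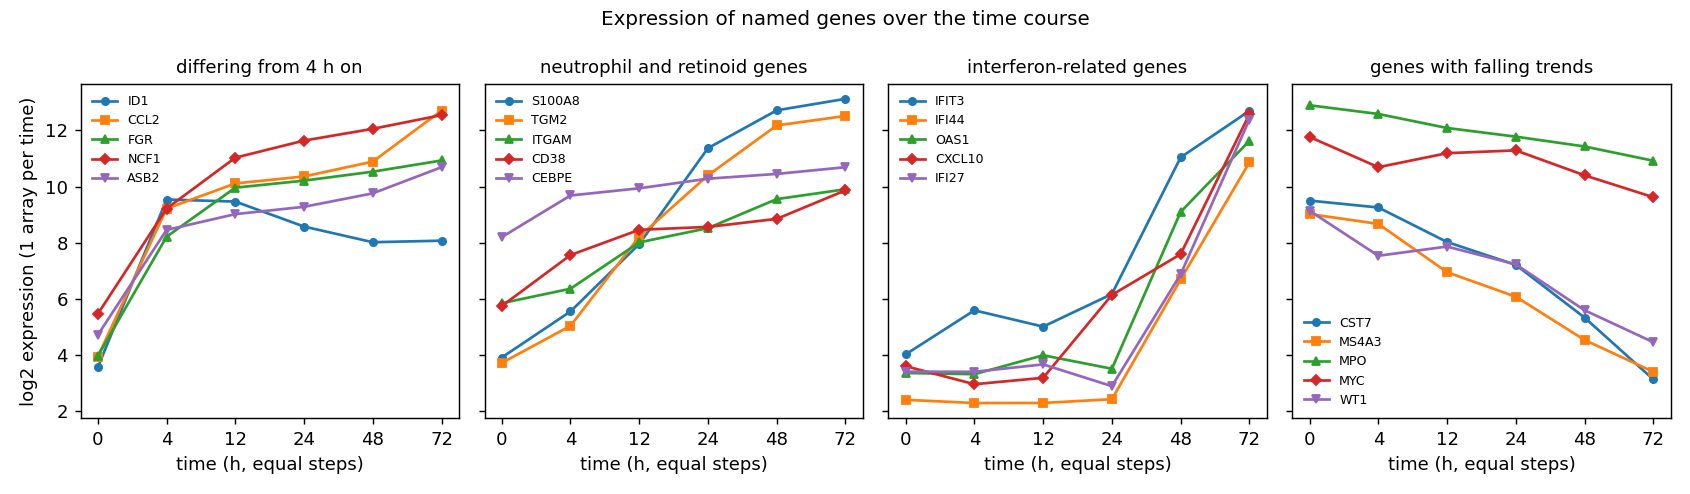
Log2 expression of named genes on the 6 arrays (points, 1 array per time; equal steps on the time axis, in h). CST7, MS4A3, MPO, MYC and WT1 have falling trends, and IFIT3, IFI44, OAS1 and IFI27 are at most 2.15 above untreated at 24 h and 8.28 to 9.0 above it at 72 h.

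Retinoid response genes had a median difference of 2.99 at 72 h, and 11 of 16 rose, also 11 adjusted over the list alone. CYP26B1 and CYP26A1, which degrade retinoic acid, were higher by 4.86 (in 1 of the 2 kept probe sets of CYP26B1) and 1.44 at 72 h, CD38 by 4.13 and ASB2 by 5.99. RARA was higher by 1.03 at 72 h but was not called. With the bioC covariate 6 members rose. Of 7 PML-RARA partners and corepressors (median -0.24), PML rose (1.44 at 72 h) and ZBTB16 (-3.33), RXRA (-1.09) and HDAC3 (-0.89) fell, also 1 and 3 adjusted over the list alone, while none passed with the covariate and only ZBTB16 without the 72 h array.

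Mature neutrophil receptors and effectors had a median of 3.19 at 72 h, and 13 of 23 rose (18 adjusted over the list alone). S100A12 and PADI4, which citrullinates histones, were higher by 7.45 and 7.30, and the integrin ITGAM by 4.07, a rise that 1 of its 2 kept probe sets shows. All 5 measured NADPH oxidase genes rose (5 adjusted over the list alone), with CYBB higher by 3.90, CYBA by 1.73, RAC2 by 1.76, NCF4 by 1.23 and NCF1 by 7.10. Without the 72 h array 9 neutrophil and 4 oxidase genes rose, and with the bioC covariate 9 and 2.

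The medians of the granule lists moved apart, with members of each list going both ways. Of 9 primary granule genes (median -1.10 at 72 h), 5 fell: CST7 (-6.38), MS4A3 (-5.63), CTSG (-2.42), MPO (-1.98) and RNASE2 (-1.10). DEFA4 rose (6.40), which makes 5 falling and 1 rising, or 5 and 2 adjusted over the list alone. CFD, PRTN3 and AZU1 differed by 2.44, 0.31 and -0.27 at 72 h without a call over all genes. The elastase ELANE stayed at or below 3.32 on the 6 arrays, under the filter, so it has no comparison. Of 14 secondary and tertiary granule genes (median 1.07), ARG1 (3.08), MMP8 (2.62) and FOLR3 (1.63) rose and the gelatinase MMP9 fell (-2.12), against 8 and 2 adjusted over the list alone. With the bioC covariate 1 rose and without the 72 h array 0, while MMP9 fell in both fits. The untreated level of 8 members, ARG1 and MMP8 among them, lay below the filter, and with these set to it the 72 h median was 0.66. LCN2, CEACAM8, OLFM4 and PTX3 of the fixed list stayed below the filter. LTF (0.60 at 72 h), PGLYRP1 (0.35) and TCN1 (-0.82) had no call over all genes and low signal on all arrays, with LTF at 4.12 or below.

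Interferon-stimulated genes had medians of 0.08, 0.23 and 0.30 at 4, 12 and 24 h, then 3.83 at 48 h and 6.80 at 72 h (the 24 h median turns negative with the shift without bioC), when all 25 members were 2-fold or more higher. Of these, 23 rose in the trend test (25 adjusted over the list alone), with IFI44 higher by 8.48, IFIT2 by 8.36 and IFIT1 by 8.33 at 72 h. The untreated level of 9 members lay below the filter, and with these set to it the 72 h median was 6.37. In the other fits 7 passed without the 72 h array, 6 with the bioC covariate and 1 within the arrays of 1 bioC level. The 28S ribosomal RNA 5' control was higher by 2.75 at 48 h and 2.86 at 72 h on the same arrays, and by 3.55 at 12 h. Antigen processing and immunoproteasome genes rose steadily (median 2.44 at 72 h, 11 of 11, also 11 adjusted over the list alone), led by PSMB9 (6.59) and the peptide transporter TAP1 (5.76), and 10 rose with the covariate.

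Inflammatory cytokines and chemokines had a median of 3.77 at 72 h, and 12 of 17 rose (13 rising and 1 falling adjusted over the list alone), among them CXCL10 (8.99), CCL2 (8.78), CCL4 (6.41) and ICAM1 (6.04). Apoptosis regulators had a median of 1.32 and 7 of 17 rose (9 adjusted over the list alone), including BCL2A1 (7.29) and CASP1 (5.03). TNFSF10, the death ligand TRAIL, differed by -1.90 at 4 h and 5.45 at 72 h without a called trend. Lysosome and autophagy genes had a median of 1.31, and 12 of 20 rose (16 adjusted over the list alone), including CTSD (4.81) and CTSS (3.48). With the bioC covariate 7, 4 and 4 members of these lists rose, and without the 72 h array 10, 4 and 5.

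Myeloid transcription factors had a median of 1.82 at 72 h. ID2 (4.86), IRF1 (3.73), MXD1 (2.92), EGR1 (2.5) and CEBPE (2.49) rose and GFI1 (-2.36) and CEBPA (-1.15) fell, or 6 and 2 adjusted over the list alone. With the bioC covariate 1 rose and 0 fell, and without the 72 h array 2 and 0. Of 10 cell cycle inhibitors (median 0.67), BTG1 rose (1.73), the only call also adjusted over the list alone, though BTG1 was not called without the 72 h array, and CDKN1A was higher by 0.73.

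MYC and ribosome biogenesis genes had a median of -1.50 at 72 h, and 12 of 17 fell (17 adjusted over the list alone), including MRTO4 (-2.38), UTP20 (-2.34) and MYC itself (-2.16). DNA replication genes had a median of -0.97, and 8 of 20 fell (16 adjusted over the list alone), including MCM4 (-1.99, in 4 of 5 kept probe sets) and GINS2 (-1.87). Of 20 mitosis genes (median -1.01), PLK1 (-1.64), CCNA2 (-1.55) and BIRC5 (-1.42) fell, also 3 adjusted over the list alone. At 48 h the MYC, replication and mitosis medians were -0.83, -0.27 and -0.11, and without the 72 h array 3, 1 and 0 genes of the MYC, replication and mitosis lists fell. With the bioC covariate 7, 5 and 0 fell, and without the 12 h array 11, 6 and 0.

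Stem and progenitor genes had a median of -1.61 over 6 members, of which GATA2 (-3.21, in 2 of 3 kept probe sets) and TERT (-2.83) fell, or 3 adjusted over the list alone. MYB differed by -2.02 at 4 h and -1.70 at 72 h and was not called, and without the 72 h array or with the bioC covariate no member was. Of 7 coagulation and fibrinolysis genes (median -1.28), TFPI (-1.33) and S100A10 (-1.32) fell, or 4 adjusted over the list alone, and TFPI was not called without the 72 h array. TFPI went from 3.74 to 2.41, below the filter, and with low values set to it the list's 72 h median was -0.08, so its place rests on low signal. Tissue factor, F3, differed by -2.08 at 4 h and -2.32 at 72 h with no called trend.

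Of 14 fixed monocyte and macrophage markers, 4 were kept. CD14, MRC1, MSR1, VCAN, LGMN, C1QA and C1QB stayed below the filter, and the others had no probe set of 1 gene. Among the 4 kept (median 1.76 at 72 h), ADGRE1 (2.28) and CD86 (1.98) rose, or 3 adjusted over the list alone, which does not speak for the markers left out. Markers of B cells (0.32), T and NK cells (0.01), erythroid cells (0.02), megakaryocytes (0.09) and fibroblasts or epithelium (-0.34) lay between percentiles 13 and 83.7 of random lists at 72 h. CD79A (1.46) rose and CD79B (-1.40) fell among B cell markers and GNLY rose (0.97) among T and NK markers, with the same counts adjusted over the list alone. With the bioC covariate, as without the 72 h array, ADGRE1 and CD79B were still called and CD86, CD79A and GNLY were not. The untreated levels of CD86, CD163 and GNLY were below the filter, so these genes entered their lists only through later, higher values. With low values set to the filter, the monocyte and macrophage median at 72 h was 1.61.

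Hypoxia genes (-0.33) and ER stress and amino acid response genes (-0.18) were within chance at 72 h but not at every time. The ER stress median was -0.63 at 12 h, below all random lists, with 4 of 13 members 2-fold lower. Both control shifts at 12 h are negative (-0.15 and -0.08), so they could only lower this median and do not test its sign. The 12 h array also had the highest 18S ribosomal RNA signal (3.92 above untreated at the 3' control). At 48 h the ER stress (-0.41) and hypoxia (-0.43) medians were at percentiles 1.17 and 1.13, and both turn positive with the shift on all controls. Against the 4 h array the median log2 difference of hypoxia at 48 h was -0.17, at percentile 27.2. LDHA fell (-0.75), also the 1 call adjusted over the list alone. PSAT1 (-3.04) and PHGDH (-2.75), of serine synthesis, fell and SLC7A11 rose (1.05), or 4 falling and 2 rising adjusted over the list alone, while SLC7A11 was not called with the bioC covariate or without the 72 h array. Cholesterol synthesis genes had medians of -0.61 at 12 h, -0.78 at 48 h (both outside the range of random lists) and -0.89 at 72 h, at percentile 4.63, and none was called over all genes or adjusted over the list alone.

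**Figure D3:**
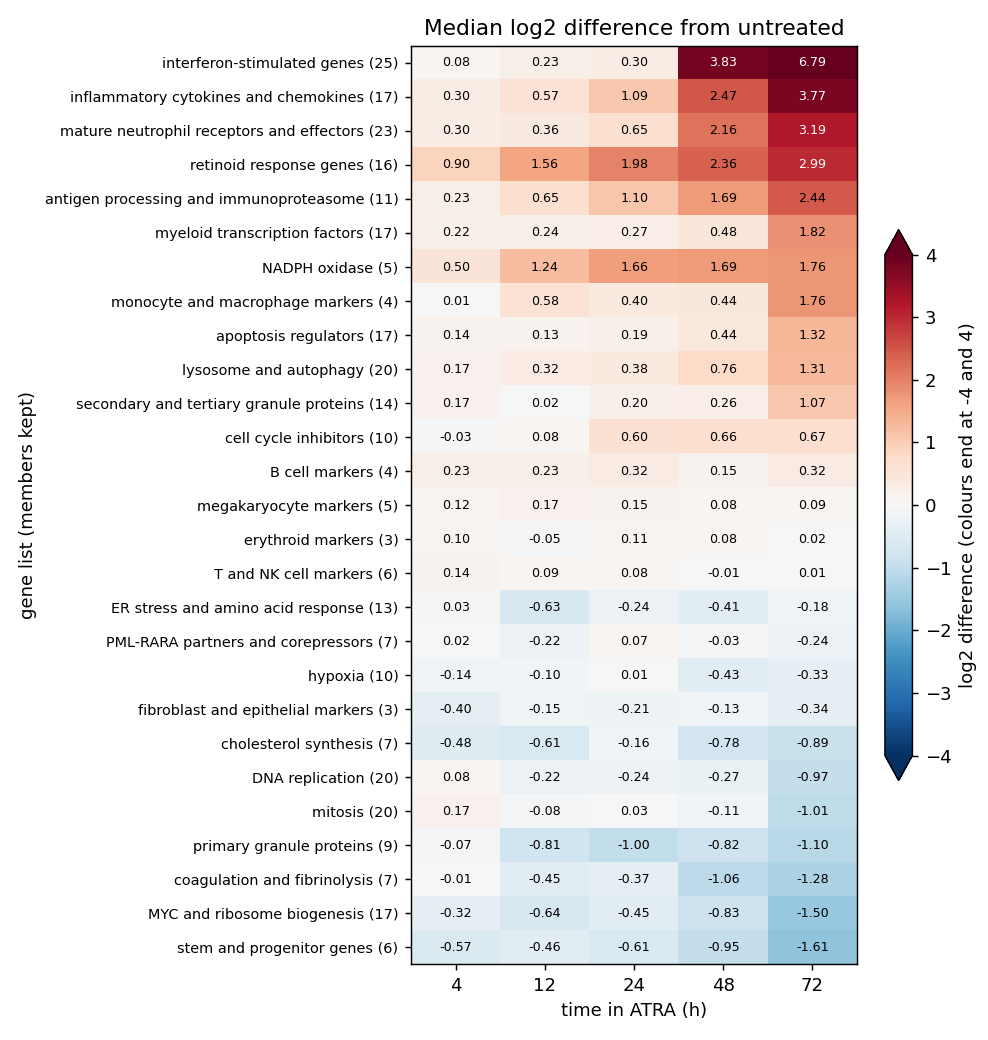
Median log2 difference from untreated (colour and number) of each gene list (vertical axis, kept members in brackets) at each time in ATRA (h). Interferon-stimulated genes go from 0.30 at 24 h to 6.80 at 72 h, and stem and progenitor genes reach -1.61.

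Correlating each list's mean profile with time order, 11 of 27 lists rose and 4 fell after Benjamini-Hochberg adjustment. The profiles of 10 rising lists were in strict order over the 6 arrays (rho = 1), for example antigen processing (r = 0.98) and retinoid response (r = 0.96). For these the two-sided exact permutation p was 0.0028 for r and rho, the smallest the 720 orders can give, and 0.0075 adjusted over 27 lists. The few kept monocyte and macrophage markers also rose by r (0.86, exact permutation p = 0.0167, adjusted 0.0346) but not by rho (0.89, adjusted 0.0643). The falling lists were MYC and ribosome biogenesis (r = -0.90, exact permutation p = 0.0083, adjusted 0.0205), DNA replication (r = -0.85, p = 0.0111, adjusted 0.0250), primary granule (r = -0.85, p = 0.0222, adjusted 0.0429) and stem and progenitor genes (r = -0.88, p = 0.0250, adjusted 0.0450). The primary granule mean fell through CST7 and MS4A3 (slopes of -1.27 and -1.19 per step), while DEFA4 rose by 1.48 per step, so it does not describe the list's members as a whole. By Spearman's rho, 12 lists passed, with MYC and DNA replication at -0.94 (adjusted exact permutation p = 0.0375) but without primary granule (-0.89, adjusted 0.0643) and stem and progenitor genes (-0.83, adjusted 0.0926). Within the 4, 24, 48 and 72 h arrays, which share a bioC level, r kept its sign in all 15 called lists, from 0.90 to 1.0 in the rising lists and from -0.95 to -0.75 in the falling ones. No test was made there, since the smallest exact p with 4 arrays is 0.0833. Without the 0 and 72 h arrays r was 0.99 for antigen processing, 0.97 for retinoid response, -0.77 for MYC and ribosome biogenesis, -0.92 for DNA replication, -0.91 for primary granule and -0.48 for stem and progenitor genes, so the last rests more on the ends. Without the 12 h array 5 lists rose and 0 fell, and with the shift on all controls 3 and 0.

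Many early differences lasted. Of the genes 2-fold higher at 4 h, including ID1, CCL2, FGR and ASB2, 149 were 2-fold higher at 12 h and 180 at 72 h. Of those lower, including TENT5C, GSAP, EBF3 and TNF, 100 and 154 were lower again. Simulated unchanged arrays against the same untreated array share 39.05 higher and 38.84 lower genes between 4 and 12 h, and independent lists 5.43 and 4.76. Between 24 and 72 h 406 higher and 218 lower genes were shared (simulated 38.66 and 37.41, independent 49.61 and 32.89), and between 48 and 72 h 750 and 540 (simulated 39.19 and 37.91, independent 86.28 and 74.31). Part of the excess over independent lists may come from the 1 shared untreated array, which the simulated comparisons also share. The simulated arrays held fewer 2-fold genes (128.2 higher and 125.0 lower at 72 h), which limits their overlaps.

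Other 4 h differences were gone by 72 h: 43 higher and 74 lower genes had come within 1.5-fold of untreated or turned. PTPRE, ADM, SLC2A3 and ANKRD37 differed by -2.88, -2.49, -2.44 and -2.08 at 4 h and by 0.78, 1.54, 0.66 and -0.49 at 72 h. CYP1A1, outside that count, was higher by 4.93 at 4 h, 0.82 at 12 h and 1.55 at 72 h. With a 2-fold difference the same way at 12 h also required, 11 higher and 14 lower genes were left.

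**Figure D4:**
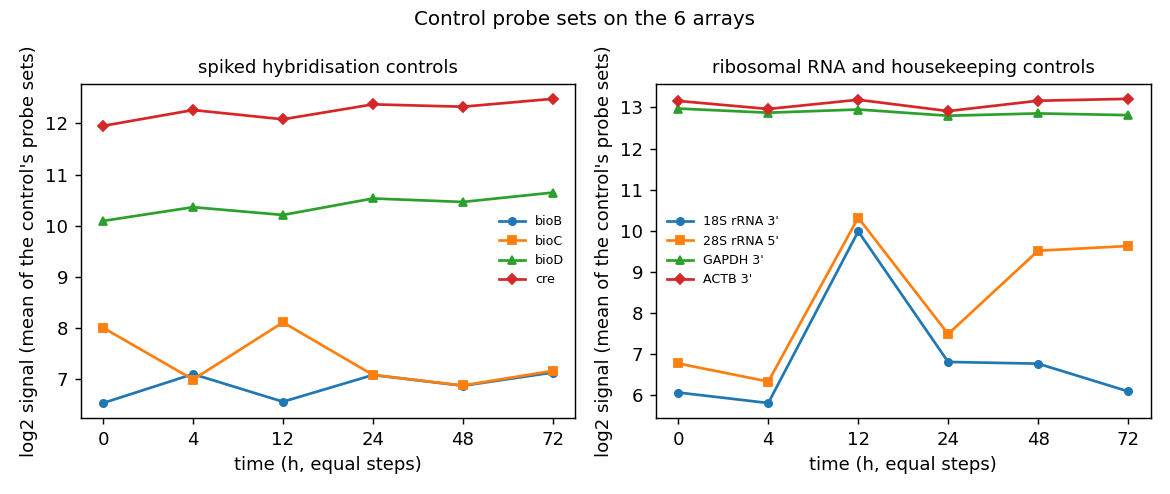
Log2 signal of control probe sets on the 6 arrays (points, mean of each control's probe sets) by time (h, equal steps). The bioC control is 8.01 and 8.11 on the 0 and 12 h arrays and 6.88 to 7.17 on the others, and the 18S 3' control reaches 9.98 at 12 h.

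Among the controls, bioC differed by 1.03 between the sets of arrays named above, with ranges of 0.10 and 0.29 within them. The other spiked controls bioB, bioD, cre and thr parted the same sets of arrays in the opposite direction. On the 0 and 12 h arrays bioB was 6.54 and 6.57, against 6.88 to 7.14 on the others, bioD 10.10 and 10.21, against 10.36 to 10.65, cre 11.95 and 12.08, against 12.26 to 12.48, and thr 6.45 and 6.20, against 6.69 to 7.09. The SD over 6 arrays was 0.54 for bioC, 0.27 for bioB, 0.21 for bioD, 0.20 for cre and 0.30 for thr, while dap, lys and phe did not part these sets. The GAPDH 3' and 5' probe sets were also higher on the 0 and 12 h arrays, at 12.91 to 12.97, against 12.60 to 12.87 on the others. The 3' minus 5' signal of GAPDH and ACTB, a measure of RNA integrity, had SDs of 0.07 and 0.05.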

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

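Of the 10 tests in the closing section, 7, on array batch, ribosomal RNA, scaling and interferon transcripts, were chosen only after their result was seen, and the test on the orders of the arrays before its result was. The other 2, on aryl hydrocarbon receptor targets and further hypoxia-inducible genes, were prompted by 4 h values of other genes, such as CYP1A1 and ADM, and set before the values of their own members were seen. For the receptor targets, the demand that the gap to the bound exceed the members' spread was applied only after the result was seen.

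Ribosomal RNA controls, which enter no gene comparison, gave signals 2-fold or more above the untreated array. At 12 h the 18S control was higher by 3.92 at its 3' probe set, 2.82 at the middle and 3.57 at the 5' probe set. The 28S 5' control was higher by 3.55 at 12 h, 2.75 at 48 h and 2.86 at 72 h, and the 28S middle control by 1.39, 1.32 and 1.30 on the same arrays. No biological explanation was tested for these signals.

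Chance order of the arrays was tested for the trend with 100 of the 360 orders, the real one always included and the others drawn at random. The real order called 2473 genes. Only 1 of the 100, the real one, called as many, which is the lowest count possible, and the highest other called 2268. That order swaps only the 12 and 24 h arrays. The test sets the real order apart from most orders drawn but not from this neighbour. It cannot tell time in ATRA from time in culture, which ran in the same order.

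The interferon-stimulated list was far above untreated at 48 and 72 h. Within the arrays of 1 bioC level, the median difference of 48 and 72 h against 4 and 24 h was 4.72. Of the members, 25 of 25 were 2-fold higher, which argues against that batch. The lowest median at 72 h under cyclic loess and both control shifts was 6.231. Each control shift moves all genes of an array alike, by 0.66 or -0.56 at 72 h, so its outcome was fixed by its size. The values show only that scaling of that size is too small to account for the list. Ribosomal RNA signal was highest at 12 h, where the list median was 0.225, and the 28S 5' control was alike at 48 and 72 h (2.75 and 2.86) while the list median went from 3.83 to 6.80, which argues against it on these few arrays. Interferon made by the cells is a candidate source that cannot be told apart from others. The median of 7 interferon genes was 3.28 at 72 h (percentile 100, 5 of 7 2-fold higher), which runs with that source. Genes were kept by their highest value, so low interferon genes may have entered through the 72 h array, which would favour a high 72 h median. At 48 h the median was 0.093, and 0 of the 7 were bright enough on the 24 and 48 h arrays to decide. Time in culture stays open, untested.

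Genes different at 4 h could reflect the bioC batch, since the 4 h and untreated arrays differ in it. On the 12 h array, which shares the untreated level, 149 of 236 higher and 100 of 246 lower genes were 2-fold different too, and the median ratio of the 12 h to the 4 h difference was 0.972 for higher and 0.61 for lower genes, against simulated batch ranges of 0.263 to 0.377 and 0.241 to 0.371. These bounds rest on a simulated profile of batch effects. Of the 59 higher and 83 lower genes back within 1.5-fold at 12 h, 6 and 10 were 2-fold again at 24 h, on an array with the 4 h bioC level, which also argues against the batch as the whole source. A batch share in single genes stays open.

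CYP1A1 was higher and several hypoxia-inducible genes lower at 4 h. CYP1A1 was lower by 3.379 or more on the 24, 48 and 72 h arrays than at 4 h, which argues against the bioC batch for that gene. The median of 6 further aryl hydrocarbon receptor targets, a list that left out CYP1A1 and CYP1B1, was -0.098 (percentile 18.6). That is under the bound of 0.2 written beforehand to count against receptor activity. But 2 were higher and 4 lower, with an SD of 0.41, more than the gap to that bound. That SD is a spread between members and not an error of the median. Its ends were CYP1A2 (-0.62) and ALDH3A1 (0.59), both of low signal. The brighter AHRR, TIPARP, NQO1 and NFE2L2 differed by -0.19, -0.002, 0.03 and -0.34, so none of these was clearly higher. The shift on all controls takes the median to 0.61 and the shift without bioC to -0.51. CYP1B1 itself was higher at 4 h, as given under other observations. Receptor activity therefore cannot be told apart from its absence. The median of 15 further hypoxia-inducible genes was -0.509, below all random lists, with 10 lower and 5 higher, which runs with lower hypoxia-type expression at 4 h, relative to other genes, as a hypothesis, though the median turns to 0.20 with the shift on all controls (-0.92 with the shift without bioC). The hypoxia list fixed beforehand was within chance at 4 h (median -0.14, percentile 7.8). Of its 10 members 7 were lower, 2 of them 2-fold (ADM -2.49 and ANKRD37 -2.08), and NDRG1 was higher by 0.92 and VEGFA by 0.77. The further genes were also low at 48 h (-0.61, percentile 0.02, or 0.39 with the shift on all controls). At 24 h they were high (0.23, percentile 99.23, or -0.25 with the shift without bioC), so their direction changed between times. Culture handling may matter and stays open.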

How the results depend on the processing

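Alternatives with the 4 h array as baseline, the bioC covariate, the arrays of 1 bioC level, no 12 h array in the list trends, the control shift without bioC and the 12 h condition on early genes were chosen after seeing the data. Counts stayed within 1.5 times under cyclic loess, no filter, the filter at percentile 75, time in hours, eBayes without an intensity trend and without x_at probe sets, except 2 falling lists under cyclic loess. At 72 h each list outside the range of random lists kept the sign of its median under every alternative run, while several lists within it, such as hypoxia, PML-RARA partners and B cell markers, did not. Signal near the filter limits low transcripts, and with no replicates no single difference was tested.

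The values cover genes higher at 4 h, genes lower at 4 h, genes higher at 12 h, genes lower at 12 h, genes higher at 24 h, genes lower at 24 h, genes higher at 48 h, genes lower at 48 h, genes higher at 72 h and genes lower at 72 h, given as higher and lower. By construction they follow the threshold. At 1.5-fold they were 892 and 919, 719 and 1290, 1112 and 1032, 1485 and 1686, and 2315 and 3126. At 3-fold they were 81 and 70, 147 and 58, 214 and 82, 422 and 174, and 890 and 581. The hybridisation control shift, which moves all genes of an array alike, gave 3182 and 52 at 4 h, 445 lower at 12 h, 4323 and 57 at 24 h, 7054 and 91 at 48 h, and 3319 and 494 at 72 h. The control shift without bioC gave 104 and 910 at 4 h, 237 and 1351 at 24 h, 1464 lower at 48 h, and 905 and 3895 at 72 h. The mean of all probe sets gave 144 lower at 4 h and 150 at 12 h. The mean of 0 and 4 h as baseline gave 208 and 134 at 12 h, and 120 and 368 lower at 24 and 48 h. The 4 h array as baseline gave 129 and 319 lower at 24 and 48 h. Where no construction is named, the cause was not tested.

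For genes with a rising trend and genes with a falling trend the counts were 747 and 3279 with the control shift without bioC, 414 and 352 on log2 hours, 440 and 269 without 72 h, 303 and 76 without 0 and 72 h, 523 and 876 with the bioC covariate, and 299 and 128 on the 4, 24, 48 and 72 h arrays. Falling genes were 47 with the hybridisation control shift, 536 without 0 h and 863 without 4 h. Fewer arrays leave fewer residual degrees of freedom. Of the 1132 rising genes all kept their direction with the covariate (497 called in both), as did all 1341 falling ones (670 called in both).

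Genes shared by 4 and 12 h were 84 higher and 211 lower with the control shift without bioC, 36 lower with the hybridisation control shift and 58 lower with the mean of probe sets. With the hybridisation control shift genes higher at both 24 and 72 h were 2240 and genes lower at both 24 and 72 h 44, and with the shift without bioC 216 and 1064. Early genes back by 72 h numbered 11 and 14 when also 2-fold at 12 h.

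Lists below percentile 2.5 were 3 at 24 h and 4 at 48 h with the 4 h array as baseline. List trends (rising and falling) were 3 and 0 with the hybridisation control shift, 6 and 0 on log2 hours and 5 and 0 without 12 h, where 5 arrays allow fewer orders. The shift without bioC gave 6 rising and cyclic loess 2 falling. On the 4, 24, 48 and 72 h arrays no list can be called, since 4 arrays allow no exact p under 0.05.

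Among lists outside the range of random lists at that time, medians changed sign under the hybridisation control shift for stem and progenitor genes (0.14, 0.22 and 0.049 at 4, 24 and 48 h), MYC and ribosome biogenesis (0.39, 0.38 and 0.17), cholesterol synthesis (0.23 and 0.22 at 4 and 48 h), apoptosis at 12 h (-0.015), DNA replication (0.58) and coagulation (0.45) at 24 h, and primary granule (0.18), hypoxia (0.57) and ER stress (0.58) genes at 48 h. Under the control shift without bioC they did so for mature neutrophil (-0.10) and inflammatory genes (-0.10) at 4 h, myeloid transcription factors (-0.21), interferon-stimulated (-0.18), apoptosis (-0.29), lysosome (-0.098) and monocyte genes (-0.22) at 24 h, and secondary granule genes at 48 h (-0.099). The apoptosis median at 12 h was -0.0059 with the mean of probe sets, -0.056 without x_at probe sets and -0.11 with the 0 and 4 h baseline. Secondary granule genes at 48 h were at -0.65 with the filter at percentile 75. With the 4 h array as baseline, stem and progenitor genes at 24 h (0.094), myeloid transcription factors at 48 h (-0.021), TENT5C at 24 h (0.98), MYB at 72 h (0.32) and CDKN2D at 72 h (-0.058) changed sign. Both shifts act on all genes of an array; for the others the cause was not tested. No paired analysis was possible because each time has 1 array.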

Other observations

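Some gene families outside the fixed lists stood apart from random lists of like expression at 72 h. Mitochondrial ribosomal proteins had a median of -0.72 (percentile 0.01, 75 genes, 22 of them 2-fold lower, 20 falling in the limma trend). Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, were at -0.62 (percentile 2.0, 29 genes, 9 falling) and zinc finger genes at -0.11 (percentile 0.34). Canonical histones had a median of 0.38 (percentile 99.85), with H2AC6 higher by 5.40, H2BC21 by 3.50, H2BC5 by 3.35 and H2BC12 by 2.76, and 4 of 19 rising. Vacuolar ATPase subunits were at 0.48 (percentile 99.75) and RAB GTPases at 0.24 (percentile 99.95). Cytosolic ribosomal proteins (-0.13, percentile 94.1), complex I subunits (-0.40, 27.2), proteasome subunits (-0.45, 22.2), tubulins (-0.45, 5.48) and solute carriers (-0.07, 25.5) were within chance. At 72 h the shift on all controls (0.66) is larger than the size of each negative median here but that of the mitochondrial ribosomal proteins, and the shift without bioC (-0.56) is larger in size than each positive one, so these signs depend on the scaling.

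Immune receptor families were higher at 72 h. Of 9 leukocyte immunoglobulin-like receptors (median 0.90), 4 rose, including LILRA5 (4.71) and LILRB2 (2.54). Of 9 SIGLEC genes (median 1.35), SIGLEC10 (2.48) and SIGLEC7 rose, and SIGLEC1 was higher by 4.52 with no called trend. The 7 interferon genes had a median of 3.28, with IFNA1 higher by 5.11 and IFNB1 by 3.85, and at 48 h the median was 0.093. IFNA probe sets may read several family members, and low interferon genes may have passed the filter only through the 72 h array. CYP1B1, an enzyme of xenobiotic metabolism, differed by 1.06 at 4 h, -2.55 at 12 h, -3.06 at 24 h and 2.06 at 72 h.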
